A study of Mus musculus with 59 samples.

How the data were processed

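The libraries came from the prefrontal cortex of 59 mouse pups and were made with a poly(A) stranded messenger RNA kit, per the labels' protocols. Reads were quantified against GRCm38 with Salmon 0.11.2 and normalized with DESeq2 1.19.11 in R 3.6.0, per the submitters' processing notes. The deposited values are therefore a normalized signal per gene, read counts divided by a size factor for each library by the authors, and are called normalized counts here. They behaved so in the table: within each library 100% of the values were whole multiples of 1 step within a tolerance of 0.01, and whole reads were recovered by dividing by that step. The recovered totals ran from 25088446 to 35858365 reads per library, and the size factors from 0.850 to 1.203. Strand-specific counting is not recorded for these values. The table held 18088 genes, 4 of them at 0 in all libraries, and 18077 identifiers matched a gene symbol in the reference names while 11 did not.

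Normalized counts plus 1 were put on the log2 scale, and 16546 genes with a mean of at least 10 were tested. The planned design had assumed raw counts and had set out the same test for normalized values, which was used. Limma 3.58.1 in R 4.3.3, with a trended and robust prior, fitted 12 group means to all 59 libraries, and 20 comparisons were drawn from that fit, each averaging the sexes with equal weight unless a sex is named. P-values were adjusted over the tested genes by the Benjamini-Hochberg method with a threshold of 0.05, and a gene past it is said to be called. As alternatives chosen after the values were seen, the recovered reads were tested with the quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0. Other alternatives were quantile normalization, no filter on the mean, a filter at 200, pseudocounts of 0.5 and 5, limma without a trend, a fit to the compared groups alone, up to 5 surrogate variables from sva 3.50.0, the replicate number as a block, and leaving out each library in turn.

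The level of Myt1l was compared by a two-sided permutation test within sex with 100000 resamples, whose smallest p is 1e-05, and within a sex by the exact permutation test. The gene lists, 31 in number, and the rule for naming genes were fixed before the data were examined, as were the comparisons. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way and compares them with no other genes. Adjustment ran over the 155 pairs of list and main comparison. In list tests added after the data were seen it ran over the 31 lists of each fit. Genes named for each of the 5 main comparisons were Myt1l, up to 12 called genes with the highest and 12 with the lowest log2 difference among those with the same sign in both sexes and leaving out predicted genes, and up to 4 members with the smallest p of each list with a camera call. The serotonin system was added for fluoxetine, and the lithium targets and Wnt targets for lithium. Where fewer than 5 genes passed, the 5 with the smallest p were named as values that did not pass, and for the other comparisons the 3 with the smallest p. The bulb and striatal gene levels named in the text, the 8 separating genes and the calls of comparisons with 5 or fewer were chosen after their values were seen.

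Markers of the olfactory bulb, 10 genes, were added after the data were seen. Of these, 7 had a mean of at least 10 in vehicle libraries (highest Cdhr1 at 583), and 0 belong to another list. The striatal list had 15 measured genes, all 15 with a vehicle mean of at least 10, and 0 belong to another list. The level of such a list in a library is the mean of the members' log2 values after standardizing each over all libraries. Genes with near-identical copies, such as ribosomal proteins, globins, mitochondrial genes with nuclear copies and pseudogenes, are uncertain because reads can be divided among the copies. Gene positions are those of GRCm38.

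Correlations of log2 differences are across genes, with a jackknife SE over libraries, and are set beside 100 simulations in which group effects were removed. Each model count was set beside 100 other divisions of the libraries into groups of the same sizes, the real one included. Scripts were tested on simulated values for the real genes with 200 genes changed. At 10 against 10, simulated changes of 1.5 and 2-fold were recovered in 89.6% and 98.5% of genes, the smallest simulated change in 64.2%, with 12 false calls. At 5 against 5 the shares were 71.6%, 92.4% and 29.9%, with 7 false calls. With no change 0 genes were called. Of the 155 pairs a moved list was called and 0 of the unmoved ones were. The simulated genes varied independently, whereas the median correlation estimated within lists in the libraries was 0.309. The simulation thus does not show how often camera calls unmoved lists in these libraries, where other divisions gave a median of 48 passing pairs. The sex markers Xist and Ddx3y matched the label in 58 of 59 libraries. No deposited sample was left out.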

Results

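Messenger RNA of the prefrontal cortex was sequenced from C57BL/6J mouse pups at postnatal day 25. Pups carried either the wild-type genotype (WT) or were labelled heterozygous (HT) for Myt1l, a neuronal zinc finger transcription factor that represses non-neuronal programs and whose loss of 1 copy causes a neurodevelopmental disorder in people. They had received vehicle, fluoxetine (a serotonin reuptake inhibitor) or lithium (a mood stabiliser) from postnatal day 3 to 24, a treatment of 3 weeks given through the mother's milk. The 59 libraries formed 12 groups of genotype, drug and sex with 5 libraries each, except 4 for WT fluoxetine females. Whole read totals recovered from the normalized table ran from 25088446 to 35858365 per library. Litters and dams are not given in the labels, so pups were treated as independent.

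Myt1l itself, the gene the HT label refers to, was examined first (chromosome 12, 29528384 to 29923213, GRCm38, ENSMUSG00000061911). Loss of 1 copy would lower its transcript if the whole message of that copy were lost, whereas Myt1l was higher in the libraries labelled HT under each drug. In vehicle pups the mean was 8030 ± 938 normalized counts in HT (SD, n = 10) against 7078 ± 255 in WT (n = 10), a log2 difference of 0.17 and a ratio of 1.14. Of the HT libraries 8 of 10 lay above the WT mean (two-sided permutation p = 0.0137). Under fluoxetine the means were 8568 ± 1166 (n = 10) and 7350 ± 534 (n = 9), a log2 difference of 0.21 (permutation p = 0.0161, 9 HT libraries above the WT mean). Under lithium they were 8706 ± 705 and 7161 ± 387 (n = 10 each), a log2 difference of 0.28 (permutation p = 5e-05, all 10 HT libraries above the WT mean). Benjamini-Hochberg adjustment over the 3 tests gave 0.0161, 0.0161 and 0.00015. Within a sex the exact permutation p was 0.151 for vehicle females, 0.0476 for vehicle males, 0.0873 and 0.143 for fluoxetine females and males, and 0.00794, the smallest 5 against 5 can give, in each sex under lithium. The limma model across all genes did not call Myt1l under any drug, with an adjusted p of 0.414, 0.590 and 0.257 for vehicle, fluoxetine and lithium. Gene-level counts cannot resolve a deleted part of the transcript, so the label is kept as given and each direction below is that of libraries labelled HT.

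**Figure D1:**
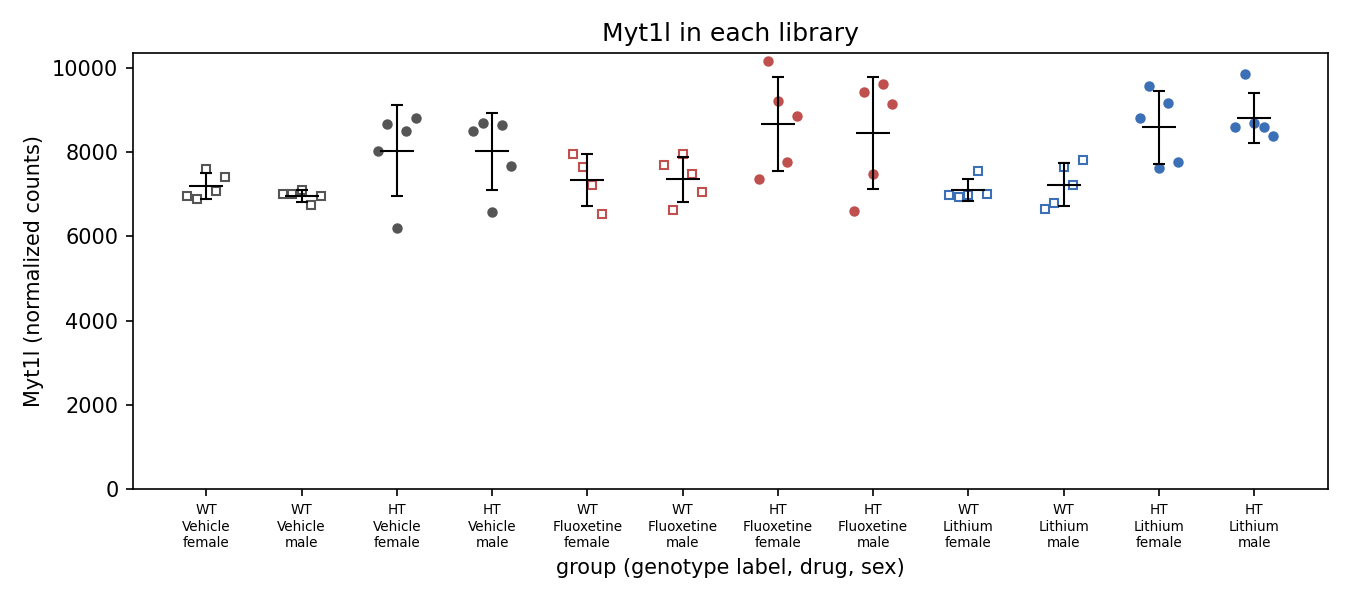
Myt1l in each library as normalized counts (y axis) by drug and sex (x axis), filled circles for libraries labelled HT and open squares for WT, with the group mean and SD as bars. HT means were 8030, 8568 and 8706 under vehicle, fluoxetine and lithium, and WT means 7078, 7350 and 7161.

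Marker genes of neighbouring brain regions varied between libraries. Eomes and Tbx21 (transcription factors of olfactory bulb projection neurons), Omp and S100a5 (mature olfactory sensory neurons and their axons), Th (the dopamine-making enzyme of bulb interneurons) and Cdhr1 (a photoreceptor and mitral cell cadherin) were higher in the fluoxetine groups. Omp averaged 189 ± 251 normalized counts in HT fluoxetine, 245 ± 238 in WT fluoxetine, 13.5 ± 6.61 in HT vehicle and 13.5 ± 10.5 in WT vehicle. Cdhr1, the most abundant of the 10 bulb markers, averaged 3711 ± 3926, 3556 ± 2663, 480 ± 416 and 686 ± 804 in the same order. All 10 markers were higher and called in both fluoxetine comparisons, with a median log2 difference of 2.60 in HT and 3.26 in WT, and 0 of 10 were called for genotype or lithium. The markers were chosen after the values were seen. Genes of striatal projection neurons, such as the dopamine and adenosine receptors Drd2 and Adora2a, were high in HT fluoxetine female 2, HT vehicle female 3, HT vehicle male 3, HT fluoxetine male 2 and WT fluoxetine female 2 (mean standardized level of the list 2.51, 2.40, 1.92, 1.88 and 1.34, next highest 0.733). Mitochondrially encoded transcripts took 8.19 ± 1.38% of the counts in HT vehicle, 6.32 ± 1.05% in HT fluoxetine and 7.26 ± 1.22% in HT lithium, against 7.69 ± 0.513%, 6.55 ± 0.809% and 7.46 ± 0.854% in WT.

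**Figure D2:**
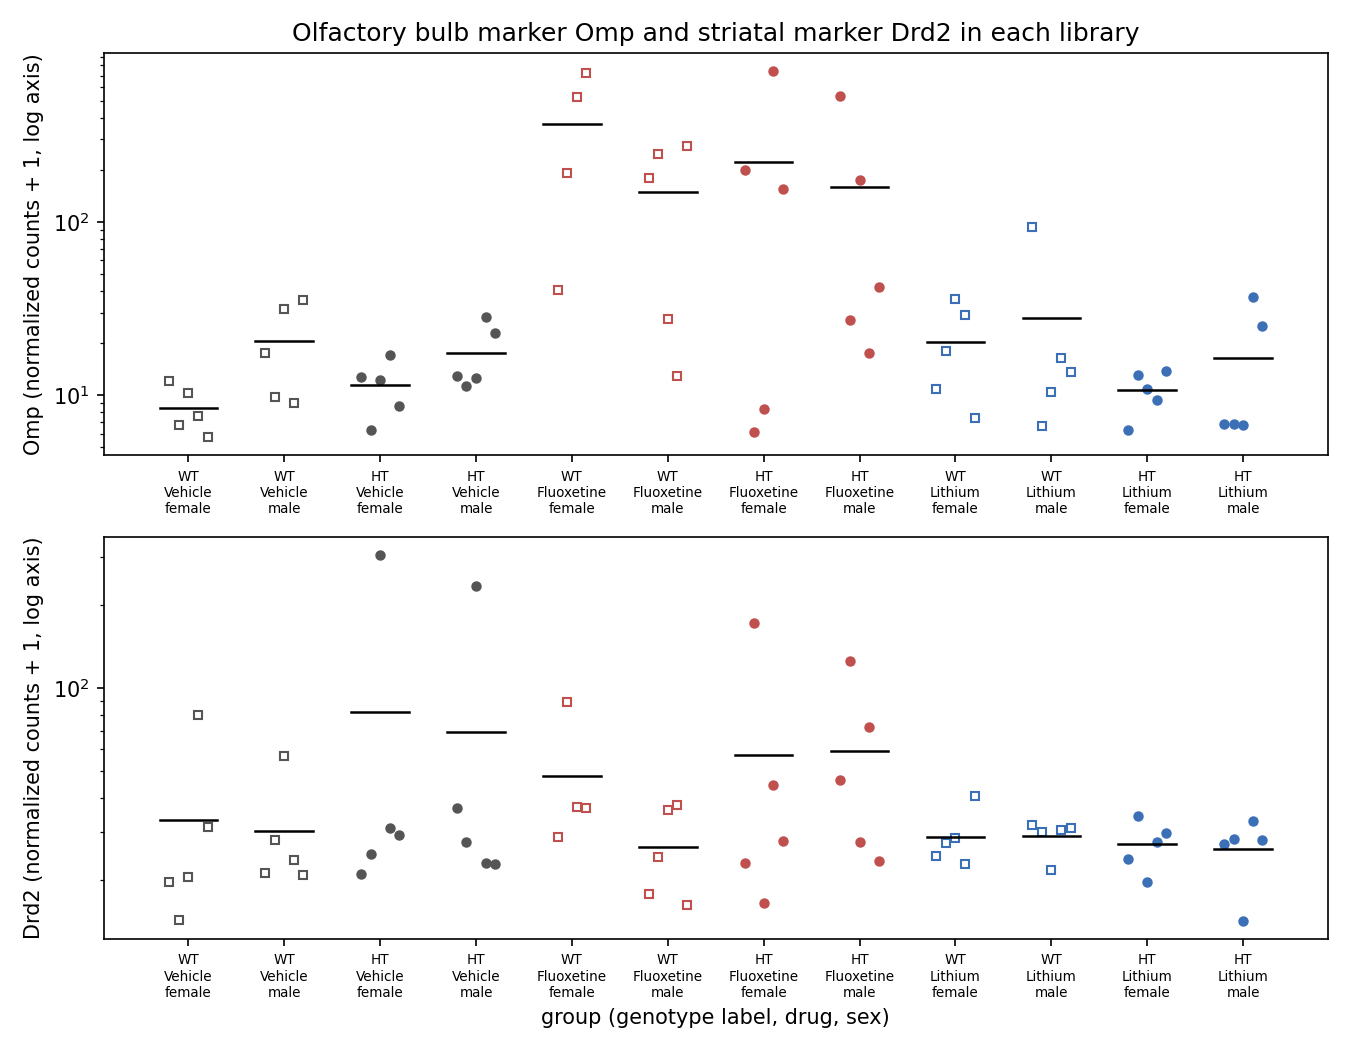
Normalized counts plus 1 (y axis, log scale) of the olfactory sensory neuron gene Omp and the striatal gene Drd2 in each library by group (x axis), with the group mean as a bar. Omp averaged 189 in HT fluoxetine and 245 in WT fluoxetine against 13.5 in each vehicle group.

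A separate division ran through the libraries and followed neither genotype nor sex alone. The 14 libraries of HT fluoxetine females, HT fluoxetine males and WT fluoxetine females stood apart from the other 45 in 8 genes whose values did not overlap. The division was itself seen in these values, and how many genes would separate other divisions was not tested. Smarcc2 and Smarca4 (subunits of the SWI/SNF chromatin remodeller) and Sltm (a chromatin-associated repressor of transcription) were higher, with Smarcc2 at 8580 ± 329 against 7272 ± 283 normalized counts. The subunit mt-Atp6 of the mitochondrial ATP synthase was lower, at 14330 ± 3257 against 48720 ± 8334. Gm28037 was higher (409 against 3.77), and Gm9794, Gm12671 and Ftl1-ps1 were lower (0.629 against 131, 71.7 against 2229 and 13.2 against 32.2). These are pseudogenes or predicted genes whose reads could be shared with parent genes, and mt-Atp6 has nuclear copies. The labels name no batch, and WT fluoxetine males were the only fluoxetine group outside the 14. HT fluoxetine thus lies wholly on one side of this division and HT vehicle on the other.

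**Figure D3:**
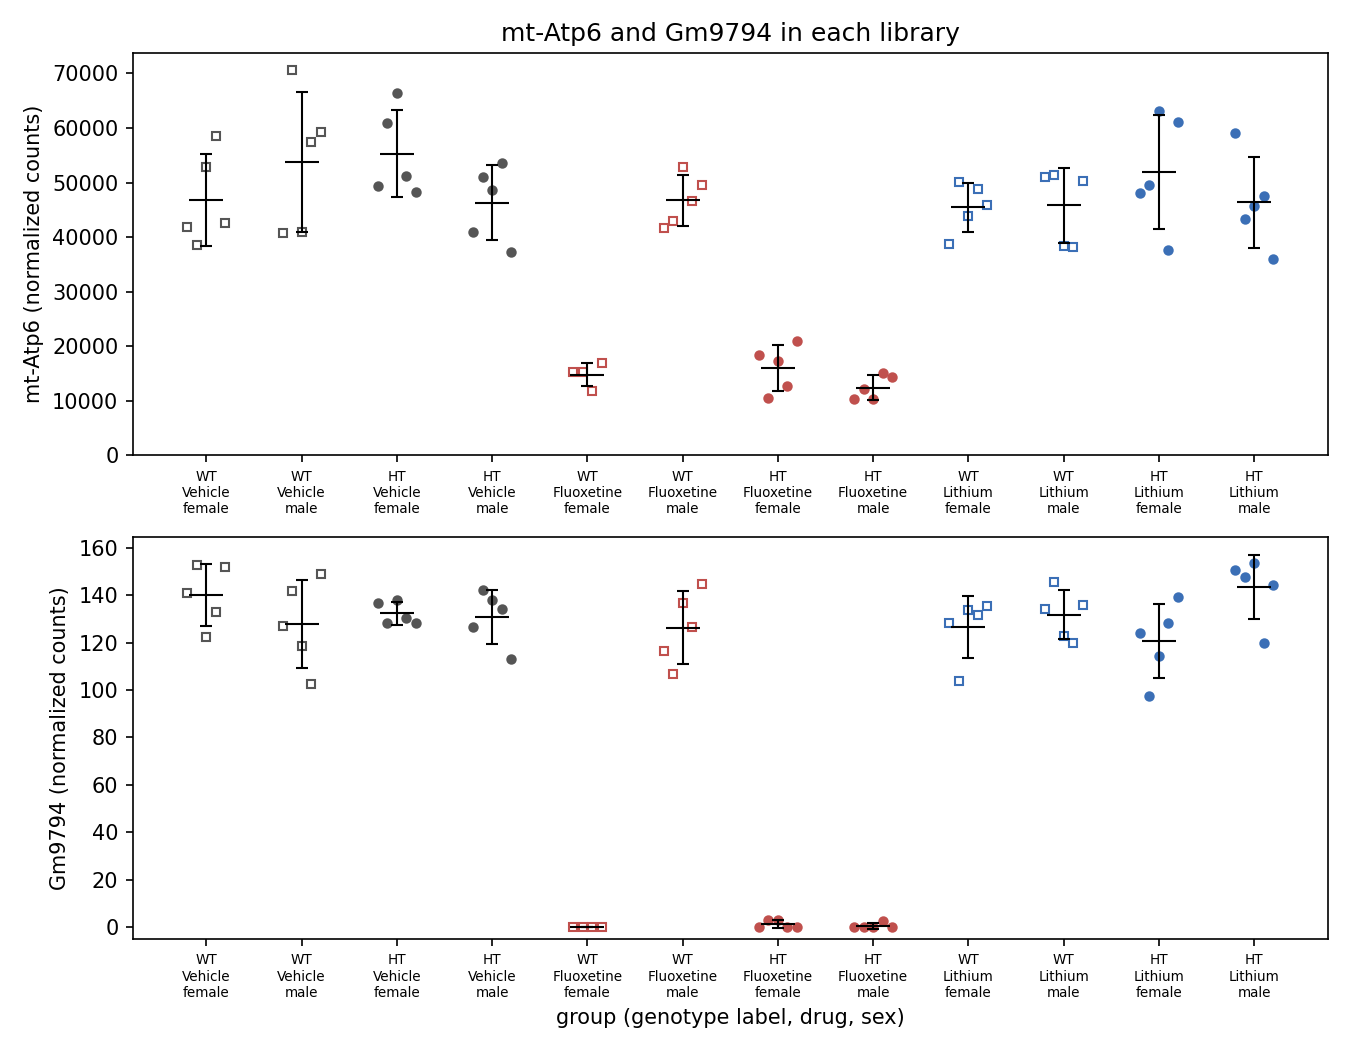
Normalized counts (y axes) of mt-Atp6 and the pseudogene Gm9794 in each library by group (x axis), with the group mean and SD as bars. The 14 libraries of HT fluoxetine and WT fluoxetine females averaged 14330 for mt-Atp6 and 0.629 for Gm9794 against 48720 and 131 in the other 45.

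What the genotype does without a drug is the first question of the design. The genes closest to a difference between HT and WT vehicle pups were Gprasp2 (a partner of G protein-coupled receptors in their sorting for degradation), Igfbp4 (a secreted binder of insulin-like growth factors), Dmgdh (a mitochondrial enzyme of choline breakdown), Nabp1 (a single-stranded DNA binder) and Loxl2 (a collagen cross-linking oxidase). Gprasp2 was 0.23 lower on the log2 scale, a difference of -0.23 (SE 0.0446, adjusted p 0.0744), and Nabp1 stood at -0.40 (SE 0.0871, adjusted p 0.0970). Igfbp4 stood at 0.33 (SE 0.0673, adjusted p 0.0803), Dmgdh at 0.97 (SE 0.203, adjusted p 0.0838) and Loxl2 at 0.52 (SE 0.123, adjusted p 0.247). Each of the 5 differed from the WT mean in the same direction in 10 of 10 HT libraries, and none passed the test. Limma called 0 of 16546 genes, with 1618 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 5. Surrogate variables gave 27, the replicate number as a block 3, quantile normalization 2 and sex taken additively 1. The count was 2 without HT vehicle female 5, 1 without HT vehicle male 1 and 3 without WT vehicle female 3.

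The fixed gene lists were set against all other genes by camera with a preset correlation of 0.01, over 31 lists in 5 comparisons. In all, 61 of the 155 pairs passed, 0 passed with an estimated correlation (lowest adjusted p 0.462) and 19 passed by fry, while other divisions of the libraries gave a median of 48 passing pairs and up to 70. In HT vehicle pups the lists of support cells lay above WT. Myelin genes had a median log2 of 0.29 over 21 genes (camera adjusted p 5.11e-06, and adjusted p = 0.669 with an estimated correlation). Oligodendrocyte precursor genes had 0.12 over 15 genes (0.0125, and adjusted p = 0.663 with an estimated correlation). Astrocyte genes had 0.13 over 19 genes (6.46e-07), microglial genes 0.13 over 18 genes (2.40e-07) and endothelial and mural genes 0.17 over 20 genes (3.12e-09). For each of these, adjusted p = 0.526 with an estimated correlation. The fractalkine receptor Cx3cr1 of microglia stood at 0.21 (SE 0.0686, adjusted p 0.376). The vascular growth factor receptor Kdr stood at 0.30 (SE 0.0915, adjusted p 0.345) and the glutamine synthetase Glul of astrocytes at 0.13 (SE 0.0570, adjusted p 0.468), and none of the 3 passed alone. Cytosolic ribosomal proteins were higher too, with a median of 0.07 over 79 genes (1.03e-09, and adjusted p = 0.663 with an estimated correlation). Cholesterol synthesis had 0.09 over 25 genes (7.36e-06, and adjusted p = 0.578 with an estimated correlation). Oxidative phosphorylation had 0.03 over 73 genes (0.0111, and adjusted p = 0.865 with an estimated correlation).

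Striatal neuron genes also lay above WT in vehicle pups, with a median log2 of 0.18 over 15 genes (camera adjusted p 0.0387, and adjusted p = 0.821 with an estimated correlation). The Notch pathway had 0.08 over 19 genes (0.0387, and adjusted p = 0.768 with an estimated correlation). Wnt targets had 0.06 over 18 genes (0.0387, and adjusted p = 0.610 with an estimated correlation). Immature neuron genes lay below, with a median of -0.09 over 25 genes (camera adjusted p 0.0356, and adjusted p = 0.787 with an estimated correlation). Gap43, a growth cone protein of extending axons, stood at -0.18 (SE 0.104, adjusted p 0.553) with the direction in 10 of 10 libraries. Autism risk genes lay below by a median of -0.04 over 80 genes (camera adjusted p 0.00150, and adjusted p = 0.663 with an estimated correlation). Of their members, the transcription regulator Tcf20 stood at -0.11 (SE 0.0432, adjusted p 0.428). No gene of any list was called over all genes. Adjusted over the list alone, 4 endothelial and mural genes passed, and 1 gene each of the Wnt target, immediate early, serotonin system, thyroid hormone response and perineuronal net lists. With surrogate variables the direction of the ribosomal list turned (adjusted p 0.898). Without HT vehicle female 3 and HT vehicle male 3, the HT vehicle libraries high in striatal genes, the camera calls left were microglia, endothelial and mural, oxidative phosphorylation and cholesterol synthesis (adjusted p 0.0272, 0.00251, 0.0272 and 0.0145). These were adjusted over the 31 lists of that fit and not over the 155 pairs.

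With 1 spread shared by all 12 groups, fluoxetine in HT pups gave the longest list of called genes against the same genotype. The order turned in a fit to the compared groups alone, with 2244 calls in HT and 3677 in WT. Barhl2, a homeobox gene of retinal and diencephalic interneurons and 1 of the 10 bulb markers, was 2.87 higher on the log2 scale (SE 0.588, adjusted p 0.000326, 10 of 10 libraries above the vehicle mean). Fosb and Fosl2, activity-induced AP-1 subunits, were higher by 0.96 (SE 0.198, adjusted p 0.000367) and 0.73 (SE 0.167, adjusted p 0.00115), each in 9 of 10 libraries. Crabp2, a retinoic acid carrier, was higher by 0.96 (SE 0.198, adjusted p 0.000327). In the mitochondrial genome mt-Atp6 stood at -1.87 (SE 0.113, adjusted p 1.59e-18) and the cytochrome oxidase subunit mt-Co2 at -1.21 (SE 0.145, adjusted p 4.06e-08), each in 10 of 10 libraries. Of cholesterol genes, Msmo1 (a sterol oxidase) stood at -0.61 (SE 0.0847, adjusted p 9.51e-07) and Stard4 (a cholesterol carrier) at -0.38 (SE 0.0449, adjusted p 2.61e-08), each in 10 of 10 libraries. Lower too were the microglial purinergic receptor P2ry12 at -0.45 (SE 0.0816, adjusted p 6.48e-05) and the growth factor receptor Csf1r at -0.37 (SE 0.0698, adjusted p 0.000107). The serotonin receptor Htr1f rose by 0.57 (SE 0.133, adjusted p 0.00118, 10 of 10 libraries).

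Limma called 4833 genes for fluoxetine in HT, 2419 higher and 2414 lower, or 29.2% of those tested, and edgeR called 4899 and DESeq2 5099. A fit to the compared groups alone gave 2244. With the 14 against 45 division as a term the count was 0 (576 at an unadjusted p under 0.05, edgeR 0). That fit takes the effect of the division from WT fluoxetine females against males, since HT has no fluoxetine library outside the 14. Of 75 named called genes 62 kept their call when any single library was left out, the genes given here among them. The surrogate variable model gave 1819 calls, of which 957 were among the 4833. A fit with the olfactory bulb markers as a covariate gave 1096, of which 1038 were among them. The first surrogate correlated with the bulb level at r -0.944 and with the division at -0.653, so these are not separate checks.

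As lists in HT fluoxetine pups, cholesterol synthesis had the smallest camera p, with 20 of 25 genes called lower over all genes, 21 adjusted over the list alone and a median of -0.29 (camera adjusted p 4.41e-13, and adjusted p = 0.523 with an estimated correlation). Microglial genes had 14 of 18 called lower, 17 adjusted over the list alone and a median of -0.28 (1.30e-08, and adjusted p = 0.526 with an estimated correlation). Immature neuron genes had 14 called higher and 1 lower, 17 adjusted over the list alone and a median of 0.34 (7.61e-06, and adjusted p = 0.526 with an estimated correlation). Among them were the actin-binding thymosin Tmsb10 at 0.40 (SE 0.0610, adjusted p 4.50e-06) and the zinc finger factor Bcl11a at 0.34 (SE 0.0643, adjusted p 0.000135). Autism risk genes had 34 called higher and 8 lower, 50 adjusted over the list alone and a median of 0.10 (0.0002, and adjusted p = 0.578 with an estimated correlation), with the chromatin remodeller Chd2 at 0.19 (SE 0.0348, adjusted p 7.24e-05). Mitochondrially encoded genes had 8 called lower and 1 higher, 9 adjusted over the list alone and a median of -0.38 over 13 genes (0.000297, and adjusted p = 0.578 with an estimated correlation). Oxidative phosphorylation had 23 lower and 5 higher, 32 adjusted over the list alone and a median of -0.07 (0.00300, and adjusted p = 0.821 with an estimated correlation), with the ATP synthase subunit Atp5e at -0.51 (SE 0.0495, adjusted p 9.13e-11). With surrogate variables the direction turned for immature neuron genes (adjusted p 0.891) and oxidative phosphorylation (0.586). In WT males, the fluoxetine group outside the 14 libraries, the medians in the order of these 6 lists were -0.12, -0.12, 0.18, 0.02, -0.08 and -0.06.

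Further lists in HT fluoxetine pups passed the set test as well. Meninges and fibroblast genes were higher (7 called, 9 adjusted over the list alone, median 0.30 over 15 genes, camera adjusted p 0.000789, and adjusted p = 0.756 with an estimated correlation). Immediate early genes were higher (6 called, 6 adjusted over the list alone, median 0.20, 0.00609, and adjusted p = 0.763 with an estimated correlation). Heat shock genes were higher (6 of 15 called, 6 adjusted over the list alone, median 0.14, 0.0475, and adjusted p = 0.768 with an estimated correlation). Endoplasmic reticulum stress genes were higher (7 called, 8 adjusted over the list alone, median 0.09 over 21 genes, 0.0455, and adjusted p = 0.821 with an estimated correlation). The chaperone Hsp90b1 among them stood at 0.20 (SE 0.0471, adjusted p 0.00137). Astrocyte genes were lower (7 called, 8 adjusted over the list alone, median -0.14, 0.00522, and adjusted p = 0.763 with an estimated correlation). The glutamate transporter Slc1a2 stood at -0.47 (SE 0.0981, adjusted p 0.000375), and at -0.06 with quantile normalization. Endothelial and mural genes were lower (9 called, 11 adjusted over the list alone, median -0.21, 0.00804, and adjusted p = 0.779 with an estimated correlation). The organic anion transporter Slco1a4 of brain capillaries stood at -0.38 (SE 0.0664, adjusted p 4.31e-05) and the pericyte regulator Rgs5 at -0.42 (SE 0.0787, adjusted p 0.000102). Myelin genes were lower by the set test (2 called, 1 adjusted over the list alone, median -0.24, 0.0377, and adjusted p = 0.877 with an estimated correlation). In WT males the medians were 0.26 for meninges and fibroblast, 0.03 for immediate early, 0.06 for heat shock and 0.04 for endoplasmic reticulum stress genes. They were 0.0033 for astrocyte, 0.0090 for endothelial and mural and 0.05 for myelin genes, so the 3 lists lower in HT were not lower there. The serotonin system did not pass (5 of 19 called, 6 adjusted over the list alone, median -0.04, camera adjusted p 0.978).

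Fluoxetine in WT pups gave calls in both directions. All 10 bulb markers were higher here (median log2 difference 3.26), and 23 of the 2464 calls were left with them as a covariate. A difference of a gene named below thus need not be one of cortical cells. Omp was higher by 3.55 (SE 0.681, adjusted p 0.00114), S100a5 by 5.02 (SE 0.944, adjusted p 0.00102) and Eomes by 4.80 (SE 1.203, adjusted p 0.00720). Slc18a2, the vesicular monoamine transporter, rose by 1.92 (SE 0.434, adjusted p 0.00375) from 15.0 ± 11.3 to 54.8 ± 34.2 normalized counts, in 9 of 9 libraries. The interneuron homeobox gene Dlx6 rose by 1.08 (SE 0.203, adjusted p 0.000933), the vesicular GABA transporter Slc32a1 by 0.58 (SE 0.118, adjusted p 0.00187) and the secreted layering protein Reln by 0.70 (SE 0.163, adjusted p 0.00427), each in 9 of 9 libraries. The cortical interneuron peptide Vip went the other way, at -0.32 (SE 0.0699, adjusted p 0.00285). The Notch effectors Hey2 and Heyl were higher by 1.01 (SE 0.201, adjusted p 0.00147) and 1.01 (SE 0.240, adjusted p 0.00521), and the Wnt-linked receptor Lgr5 by 1.94 (SE 0.497, adjusted p 0.00819, -0.05 with surrogate variables). Of red cell genes, the globin Hba-a2 was higher by 0.79 (SE 0.202, adjusted p 0.00790) and the anion exchanger Slc4a1 by 1.22 (SE 0.330, adjusted p 0.0107). The clock output factors Dbp at -0.32 (SE 0.0868, adjusted p 0.0116) and Nr1d1 at -0.34 (SE 0.0835, adjusted p 0.00622) were lower. Htr1f rose by 0.53 (SE 0.137, adjusted p 0.00817), and mt-Atp6 stood at -0.92 (SE 0.116, adjusted p 1.01e-06). The mean log2 value of mt-Atp6 went from 15.5 to 13.84 in WT females, inside the 14 libraries. In WT males, outside them, it went from 15.68 to 15.51.

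Limma called 2464 genes for fluoxetine in WT, 1458 higher and 1006 lower, with edgeR at 2517 and DESeq2 at 2726. A fit to the compared groups alone gave 3677. The count was 1086 without WT fluoxetine female 4 and 1373 without WT fluoxetine male 2. In females alone, an added comparison, 3272 genes were called, and in males alone 0 (edgeR 0, DESeq2 0). In males 800 genes, or 4.835%, had an unadjusted p under 0.05, no more than chance gives at that threshold. A test of that difference between the sexes called 14 genes (edgeR 16, DESeq2 77). With the 14 against 45 division as a term the count was 0 (990 at an unadjusted p under 0.05, edgeR 0), with the bulb markers as a covariate 23 (all among the 2464) and with surrogate variables 251 (83 among the 2464). Of 73 named called genes 60 kept their call when any single library was left out, the genes given here among them. Across the 4833 genes called in HT, the fluoxetine difference in WT males had the same sign in 84.9%, where 1 of 100 simulations without effect was as high (median 54.75%, highest 87.2%).

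By list in WT fluoxetine pups, cholesterol synthesis was lower (16 of 25 called, 17 adjusted over the list alone, median -0.20, camera adjusted p 1.05e-09, and adjusted p = 0.526 with an estimated correlation). Of its genes, Msmo1 stood at -0.43 (SE 0.0873, adjusted p 0.00154). Microglial genes were lower (9 called, 12 adjusted over the list alone, median -0.22, 7.42e-07, and adjusted p = 0.526 with an estimated correlation). Immature neuron genes were higher (10 called, 14 adjusted over the list alone, median 0.26, 1.2e-05, and adjusted p = 0.526 with an estimated correlation). GABAergic neuron genes were higher as well (10 of 23 called higher and 3 lower, 16 adjusted over the list alone, median 0.11, 0.0422, and adjusted p = 0.526 with an estimated correlation). Circadian clock genes were lower (5 of 16 called, 5 adjusted over the list alone, median -0.13, 0.00104, and adjusted p = 0.526 with an estimated correlation). Mitochondrially encoded genes were lower (6 called and 1 higher, 9 adjusted over the list alone, median -0.32, 0.000297, and adjusted p = 0.578 with an estimated correlation). Oxidative phosphorylation was lower (7 called and 1 higher, 8 adjusted over the list alone, median -0.04, 0.0467, and adjusted p = 0.901 with an estimated correlation). Meninges and fibroblast genes were higher (4 called, 4 adjusted over the list alone, median 0.24, 0.00121, and adjusted p = 0.763 with an estimated correlation). Erythrocyte genes were higher (4 of 10 called, 7 adjusted over the list alone, median 0.44, 0.0180, and adjusted p = 0.578 with an estimated correlation), and the Notch pathway was too (5 called, 5 adjusted over the list alone, median 0.16, 0.00673). For the Notch pathway, adjusted p = 0.663 with an estimated correlation. Wnt targets were higher (5 called, 6 adjusted over the list alone, median 0.14, 0.0300, and adjusted p = 0.578 with an estimated correlation). Autism risk genes were the last of the higher lists (17 called higher and 2 lower, 25 adjusted over the list alone, median 0.04, 0.0175, and adjusted p = 0.768 with an estimated correlation). With surrogate variables the direction turned for immature neuron genes (adjusted p 0.0683), oxidative phosphorylation (0.656), the Notch pathway (0.457) and Wnt targets (0.629). In WT females, inside the 14 libraries, and WT males, outside them, the medians were -0.30 and -0.12 for cholesterol synthesis, -0.29 and -0.12 for microglia and 0.36 and 0.18 for immature neuron genes. They were -0.52 and -0.08 for mitochondrially encoded and 0.21 and 0.02 for Notch pathway genes, 0.08 and 0.02 for autism risk genes and -0.01 and -0.06 for oxidative phosphorylation. For GABAergic, clock, meninges, erythrocyte and Wnt lists they were 0.11 and 0.12, -0.14 and -0.14, 0.25 and 0.26, 0.46 and 0.42, and 0.16 and 0.13. The serotonin system did not pass (3 of 19 called, 5 adjusted over the list alone, median -0.08, camera adjusted p 0.987).

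Whether fluoxetine acts differently in the genotypes was tested by their interaction. The gene mt-Atp6, a mitochondrial ATP synthase subunit, had an interaction of -0.95 (SE 0.162, adjusted p 0.00259), and the remaining calls were the pseudogenes or predicted genes Gm9794, Gm10221, Gm3883 and Gm12671, named here although chosen after their values were seen. All 5 calls, each lower, belong to genes with near-identical copies, and the WT fluoxetine group straddles the division of 14 against 45. Limma called 5 genes, with 454 at an unadjusted p under 0.05, edgeR 1 and DESeq2 3. A fit to the compared groups alone gave 3, and with sex taken additively it was 0, with or without the division as a term. The count was 3 without any single one of HT fluoxetine female 1, HT fluoxetine male 3, HT fluoxetine male 5 or WT fluoxetine female 4. Between HT and WT pups that both had fluoxetine, Rasgrp4, an exchange factor for Ras in mast cells, was higher by 0.58 (SE 0.119, adjusted p 0.0260), while the neuronal oxygen carrier Ngb at -0.82 (SE 0.186, adjusted p 0.0869) did not pass. That comparison called 7 genes, 1 higher and 6 lower (edgeR 4, DESeq2 9). In females alone, within the division, limma called 0 (edgeR 0, DESeq2 3) and in males, across it, 302 (edgeR 220, DESeq2 493). With both sexes limma called 0 with the division as a term and 103 with surrogate variables. Across genes, which are not independent replicates, the fluoxetine differences in HT and WT correlated with Pearson r 0.788 (jackknife SE 0.0801, Spearman rho 0.769), above every 1 of 100 simulations without effect (-0.52 to 0.34). The r was 0.813 against WT females and 0.462 against WT males, where simulations ran from -0.44 to 0.45. With the bulb markers as a covariate the r was 0.641 and 0.106, and no simulations were run with that covariate. Of the calls, 1163 were shared as higher (213 for independent lists) and 841 as lower (147 for independent lists).

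The question of lithium in HT pups was asked next. Fkbp5, the co-chaperone induced by the glucocorticoid receptor, rose by 0.81 on the log2 scale (SE 0.111, adjusted p 8.61e-06) from 651 ± 157 to 1125 ± 147 normalized counts. Zbtb16, a zinc finger factor induced by the same receptor, rose by 0.69 (SE 0.0978, adjusted p 1.55e-05), each in 10 of 10 libraries. Igfbp3, a binder of insulin-like growth factors, rose by 0.69 (SE 0.116, adjusted p 0.000306). Alkal2, a ligand of the ALK receptor, rose by 0.67 (SE 0.146, adjusted p 0.00636) and the receptor transporter Rtp1 by 1.21 (SE 0.289, adjusted p 0.0149). The disulfide isomerase Pdia3 rose by 0.23 (SE 0.0522, adjusted p 0.00968) and the chaperone Hyou1 by 0.26 (SE 0.0601, adjusted p 0.0115). Depp1, a FOXO-induced autophagy regulator, fell by 1.06 (SE 0.206, adjusted p 0.00169) and Tmem252 by 0.72 (SE 0.142, adjusted p 0.00225). The angiopoietin receptor Tek fell by 0.41 (SE 0.0758, adjusted p 0.00103), Kdr by 0.44 (SE 0.0915, adjusted p 0.00401) and Lef1, a Wnt transcription factor of brain endothelium and thalamus, by 0.65 (SE 0.121, adjusted p 0.000944). The ribosomal proteins Rpl17, Rpl9 and Rps27a fell by 0.43 (SE 0.0554, adjusted p 2.22e-06), 0.37 (SE 0.0516, adjusted p 9.08e-06) and 0.35 (SE 0.0557, adjusted p 0.000105), each in 10 of 10 libraries, although such genes have many processed copies. P2ry12 fell by 0.37 (SE 0.0816, adjusted p 0.00707), Ly86, a microglial partner of toll-like receptors, by 0.34 (SE 0.0691, adjusted p 0.00277), and the light-strand gene mt-Nd6 by 0.84 (SE 0.195, adjusted p 0.0125).

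Limma called 470 genes for lithium in HT, 210 higher and 260 lower (edgeR 475, DESeq2 701). The control group held the HT vehicle libraries high in striatal genes, and the count was 177 without HT vehicle female 3, 205 without HT vehicle male 3 and 102 without both. It was also 271 without HT vehicle female 1, 256, 246 and 721 without HT lithium females 1, 2 and 3, and 280 and 241 without HT lithium males 1 and 2. Of 46 named called genes 22 kept their call when any single library was left out, the genes given here among them. With the spread taken from the HT vehicle and lithium libraries alone the count was 188, and Kdr and P2ry12 were no longer called. Surrogate variables gave 1001.

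As lists in HT lithium pups, cytosolic ribosomal proteins were lower, with 17 of 79 called, 43 adjusted over the list alone and a median of -0.14 (camera adjusted p 1.37e-27, and adjusted p = 0.526 with an estimated correlation). Endoplasmic reticulum stress genes were higher (5 called, 14 adjusted over the list alone, median 0.18, 9.50e-12, and adjusted p = 0.462 with an estimated correlation). Myelin genes were lower as a set (0 called, 18 adjusted over the list alone, median -0.56, 1.01e-10, and adjusted p = 0.526 with an estimated correlation). Oligodendrocyte precursor genes were lower (0 called, 4 adjusted over the list alone, median -0.21, 3.93e-05, and adjusted p = 0.526 with an estimated correlation). Microglia (5 called, 8 adjusted over the list alone, median -0.18, 4.30e-09), endothelial and mural cells (6 called, 9 adjusted over the list alone, median -0.19, 1.86e-07) and astrocytes (2 called, 9 adjusted over the list alone, median -0.17, 4.36e-07) were lower, with adjusted p = 0.526 with an estimated correlation for each. Mitochondrially encoded genes were lower (1 called, 1 adjusted over the list alone, median -0.22, 0.000440, and adjusted p = 0.578 with an estimated correlation). So was cholesterol synthesis (1 called, 2 adjusted over the list alone, median -0.10, 8.41e-05, and adjusted p = 0.648 with an estimated correlation). Cell cycle genes were lower with no gene called (0 adjusted over the list alone, median -0.13, 0.0111, and adjusted p = 0.732 with an estimated correlation). The Notch pathway was lower in the same way (0 adjusted over the list alone, median -0.12, 0.0332, and adjusted p = 0.763 with an estimated correlation). Wnt targets were lower (2 called, 2 adjusted over the list alone, median -0.11, 0.0332, and adjusted p = 0.578 with an estimated correlation). Perineuronal net genes were lower (1 of 13 called, 1 adjusted over the list alone, median -0.10, 0.0363, and adjusted p = 0.526 with an estimated correlation). Glucocorticoid response genes were higher (4 of 17 called, 8 adjusted over the list alone, median 0.03, 0.0411, and adjusted p = 0.768 with an estimated correlation). Erythrocyte genes were higher (0 called, 3 adjusted over the list alone, median 0.25, 0.0198, and adjusted p = 0.578 with an estimated correlation). Lithium targets and inositol enzymes did not pass (0 of 15 called, 1 adjusted over the list alone, median 0.04, camera adjusted p 0.399). Of these, the inositol monophosphatase Impa1, which lithium inhibits, stood at 0.18 (SE 0.0544, adjusted p 0.0611) and the protein kinase C substrate Marcks at -0.19 (SE 0.0745, adjusted p 0.159). With surrogate variables the direction of the cell cycle list turned (adjusted p 0.934). The HT vehicle controls of this comparison had themselves stood above WT in the ribosomal, myelin, oligodendrocyte precursor, astrocyte, microglial and endothelial lists (medians 0.07, 0.29, 0.12, 0.13, 0.13 and 0.17). Under lithium in WT the medians of the same lists were 0.05, -0.30, -0.0056, -0.02, -0.01 and -0.03. The cholesterol synthesis, Notch pathway and Wnt target lists had also stood above WT in HT vehicle pups. Under lithium in WT females and males their medians were -0.05 and 0.02, 0.07 and 0.01, and 0.05 and -0.007.

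The same drug was then followed in WT pups. Nptx2, an activity-induced pentraxin that clusters AMPA receptors, rose by 0.53 (SE 0.0701, adjusted p 1.24e-05) from 1123 ± 124 to 1610 ± 112 normalized counts in 10 of 10 libraries. Zbtb16 and Fkbp5 rose by 0.54 (SE 0.0978, adjusted p 0.00158) and 0.52 (SE 0.111, adjusted p 0.00826), and Smad6, an inhibitor of bone morphogenetic protein signals, by 0.66 (SE 0.144, adjusted p 0.00867), each in 10 of 10 libraries. The stress transcription factor Atf4 rose by 0.29 (SE 0.0515, adjusted p 0.00104), the lectin chaperone Calr by 0.24 (SE 0.0565, adjusted p 0.0163) and the carbonic anhydrase Car12 by 0.45 (SE 0.0992, adjusted p 0.00826). Depp1 fell by 0.997 (SE 0.206, adjusted p 0.00575), Klf10, an early target of transforming growth factor beta, by 0.59 (SE 0.129, adjusted p 0.00890) and Vegfc, a lymphatic growth factor, by 0.41 (SE 0.0891, adjusted p 0.00826). The clock repressors Per1, Nr1d1, Nr1d2 and Bhlhe40 fell by 0.32 (SE 0.0640, adjusted p 0.00381), 0.42 (SE 0.0810, adjusted p 0.00306), 0.23 (SE 0.0451, adjusted p 0.00394) and 0.39 (SE 0.0776, adjusted p 0.00394), each in 10 of 10 libraries. In HT lithium pups Nr1d1 stood at -0.37 (SE 0.0810, adjusted p 0.00605), while Per1 at -0.17 (adjusted p 0.132), Nr1d2 at -0.10 (0.224) and Bhlhe40 at -0.07 (0.697) were not called, and the clock list did not pass there (camera adjusted p 0.380).

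Limma called 266 genes for lithium in WT, 164 higher and 102 lower (edgeR 241, DESeq2 396). A fit to the compared groups alone gave 617, surrogate variables 844 and the bulb markers as a covariate 453. The count was 173, 134, 148 and 111 without WT vehicle female 1, WT vehicle female 4, WT vehicle male 1 and WT vehicle male 5, and 144 without WT lithium female 3. Of 34 named called genes 17 kept their call when any single library was left out, the genes given here among them. Oxidative phosphorylation was higher as a set (2 called, 13 adjusted over the list alone, median 0.09, camera adjusted p 4.41e-12, and adjusted p = 0.526 with an estimated correlation). Endoplasmic reticulum stress genes were higher (5 called, 11 adjusted over the list alone, median 0.19, 9.71e-12, and adjusted p = 0.462 with an estimated correlation). Circadian clock genes were lower (5 called, 10 adjusted over the list alone, median -0.11, 7.36e-06, and adjusted p = 0.462 with an estimated correlation). Glucocorticoid response genes were higher (3 called, 6 adjusted over the list alone, median 0.12, 0.0347, and adjusted p = 0.763 with an estimated correlation). Myelin genes were lower (0 called, 0 adjusted over the list alone, median -0.30, 1.95e-05, and adjusted p = 0.732 with an estimated correlation). Erythrocyte genes were higher (0 called, 0 adjusted over the list alone, median 0.25, 0.0198, and adjusted p = 0.578 with an estimated correlation). Mitochondrially encoded genes were lower (1 called, 1 adjusted over the list alone, median -0.11, 0.0458, and adjusted p = 0.788 with an estimated correlation). Cytosolic ribosomal proteins were higher as a set (median 0.05, 0.00739, and adjusted p = 0.877 with an estimated correlation), although the 1 called gene, Rpl17, was lower and the direction of the list turned with surrogate variables (adjusted p 0.934). In WT females and males the medians were -0.54 and -0.07 for myelin, 0.39 and 0.10 for erythrocyte, 0.25 and 0.10 for endoplasmic reticulum stress and -0.07 and -0.14 for clock genes, so the pooled myelin value came mostly from females. Lithium targets and inositol enzymes did not pass (0 called, 0 adjusted over the list alone, median 0.0029, camera adjusted p 0.898), with the inositol synthase Isyna1 at 0.21 (SE 0.0898, adjusted p 0.257). Wnt targets did not pass (median 0.03, camera adjusted p 0.827), with Lef1 at -0.30 (SE 0.121, adjusted p 0.220).

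**Figure D4:**
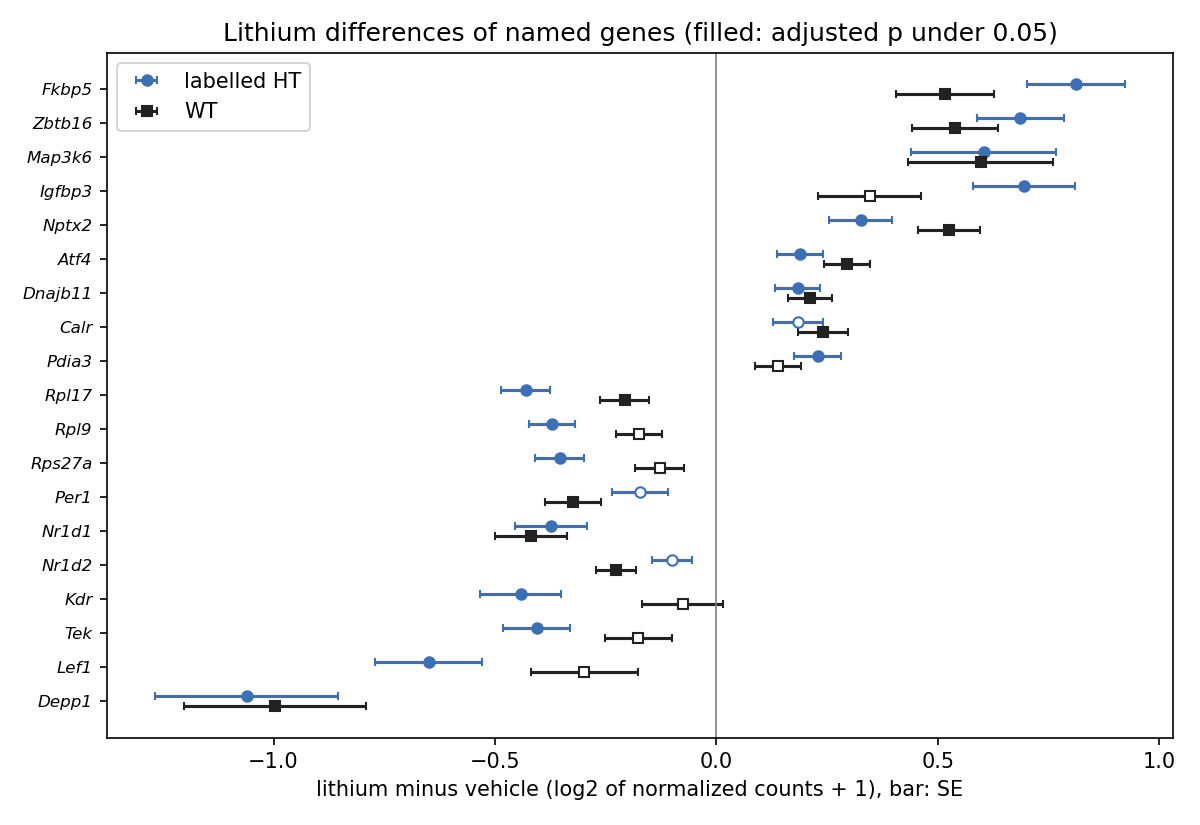
Lithium minus vehicle log2 difference with its SE (x axis) of 19 genes (y axis) in libraries labelled HT and in WT, filled where the limma adjusted p was under 0.05. Fkbp5 stood at 0.81 in HT and 0.52 in WT, and Depp1 at -1.06 and -0.997.

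The genotypes were then compared for their response to lithium. The genes closest were Rpl32, a large-subunit ribosomal protein, at an interaction of -0.29 (SE 0.0672, adjusted p 0.860) and Abi3, an actin regulator of microglia, at -0.65 (SE 0.155, adjusted p 0.860), and neither passed. Limma called 0 genes, with 829 at an unadjusted p under 0.05, edgeR 0 and DESeq2 0. Between HT and WT pups under lithium, Rpl17 stood at -0.27 (SE 0.0554, adjusted p 0.0895) and Trim71, a developmental ubiquitin ligase, at -0.72 (SE 0.167, adjusted p 0.319). Limma called 1 gene there, the pseudogene Gm15500 at -0.20 (SE 0.0363, adjusted p 0.0221), edgeR 1 and DESeq2 2. Surrogate variables gave 94, quantile normalization 2, a fit to the compared groups alone 2 and sex taken additively 0. The count was 0 without any single one of HT lithium female 5, HT lithium males 2 and 4, WT lithium females 1, 2 and 3, and WT lithium males 2, 3 and 5, 3 without HT lithium female 1 or HT lithium male 1, and 2 without WT lithium female 4 or 5. Across genes the lithium differences in HT and WT correlated with Pearson r 0.316 (jackknife SE 0.126, Spearman rho 0.364), and 5 of 100 simulations without effect (-0.45 to 0.48) were as high. Of the calls, 61 were shared as higher (2.08 for independent lists) and 33 as lower (1.60 for independent lists).

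Whether a drug returned HT pups to the WT vehicle state was asked directly. Against WT vehicle, HT fluoxetine pups showed mt-Atp6 at -1.84 (SE 0.113, adjusted p 2.80e-18), the ribosomal protein Rpl24 at -0.49 (SE 0.0391, adjusted p 6.94e-14) and Myt1l at 0.26 (SE 0.0629, adjusted p 0.00164). Against the same controls HT lithium pups showed Rpl17 at -0.48 (SE 0.0554, adjusted p 1.13e-07), Nptx2 at 0.57 (SE 0.0701, adjusted p 4.67e-07), Igfbp4 at 0.48 (SE 0.0673, adjusted p 1.14e-05) and Myt1l at 0.30 (SE 0.0629, adjusted p 0.00465). Limma called 4923 genes for HT fluoxetine (2382 higher, 2541 lower, edgeR 4961, DESeq2 5141), 0 with the division as a term and 901 with the bulb markers as a covariate, and 398 for HT lithium (239 higher, 159 lower, edgeR 349, DESeq2 516). A fit to the compared groups alone gave 3147 and 695, and surrogate variables 1813 and 1329. The lithium count was 244 without HT lithium male 2, 258 without WT vehicle female 1, 251 without WT vehicle male 1 and 239 without WT vehicle male 5. The genotype difference in vehicle pups and the drug difference in HT pups use the same HT vehicle libraries. Their Pearson r across genes was -0.23 for fluoxetine (jackknife SE 0.208), where simulations without effect averaged -0.49, and -0.45 for lithium (jackknife SE 0.213), where they averaged -0.50. With the shared libraries split into separate parts the r was -0.01 and -0.04. The covariances were -0.0122 against a simulated -0.0108 and -0.0125 against -0.0113, so no reversal beyond that of shared controls was detected.

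**Figure D5:**
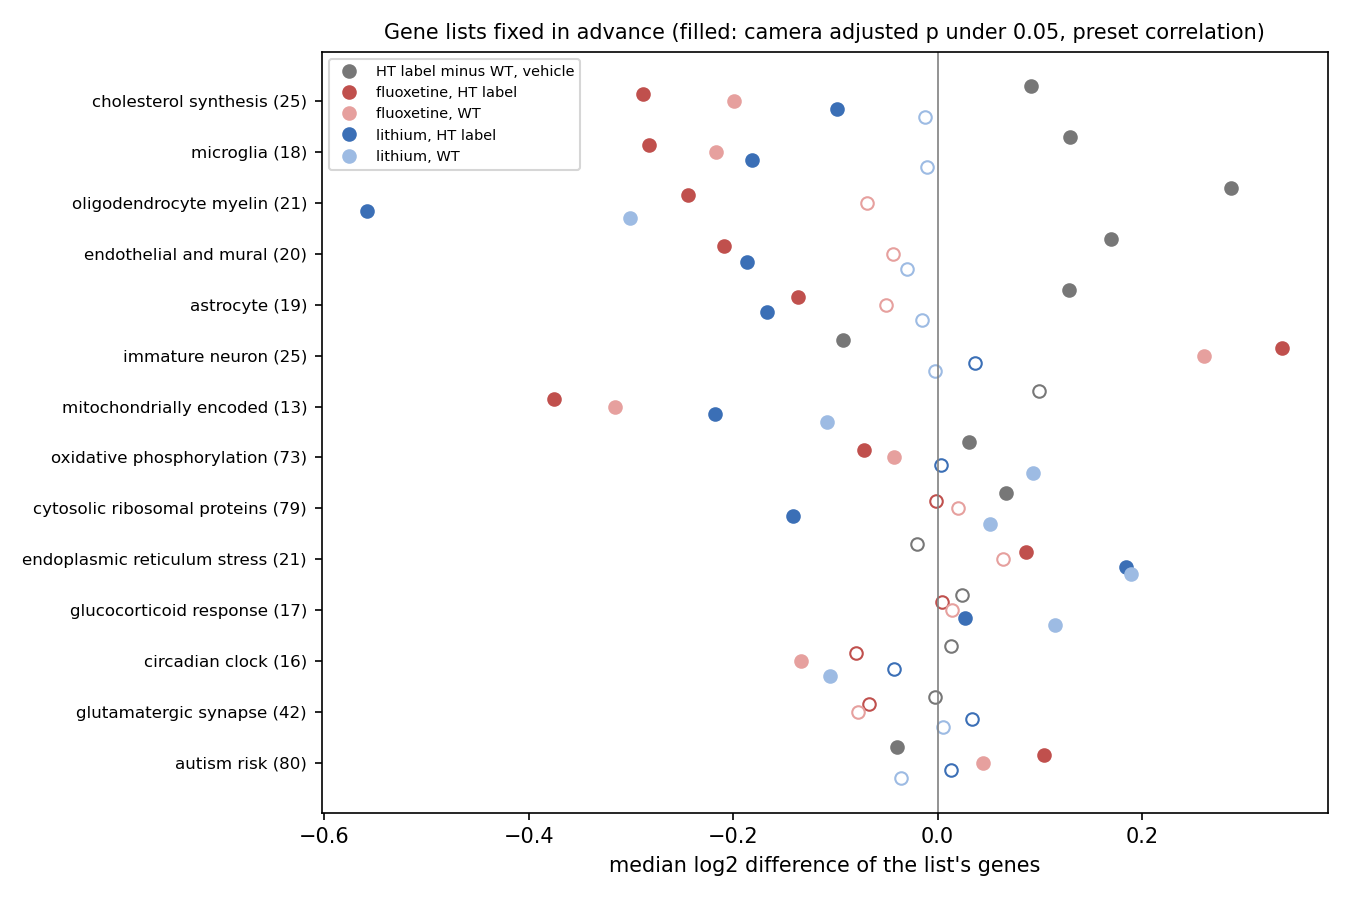
Median log2 difference (x axis) of 14 gene lists (y axis) in the 5 main comparisons, filled where camera with a preset correlation gave an adjusted p under 0.05. Cholesterol synthesis stood at -0.29 and -0.20 for fluoxetine in HT and WT, and endoplasmic reticulum stress at 0.18 and 0.19 for lithium.

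The sexes were compared within HT pups. In females Rpl24 stood at -0.63 and mt-Atp6 at -1.83 after fluoxetine, and in males mt-Atp6 at -1.91. After lithium the lower ribosomal proteins were Rpl17 at -0.46 and Rpl9 at -0.44 in females and Rpl17 at -0.40 in males, where Zbtb16 stood at 0.67 and Depp1 at -1.39 (adjusted p 0.0497 for each of these male genes). For fluoxetine limma called 1134 genes in females (533 higher, 601 lower, edgeR 1164, DESeq2 1547) and 2222 in males (1103 higher, 1119 lower, edgeR 2319, DESeq2 2602). A fit to the compared groups alone gave 19 and 7, and the bulb markers as a covariate 439 and 46. Surrogate variables gave 1647 and 238. The female count was 539 without HT fluoxetine female 4 and 706 without HT vehicle female 1. The male count was 426, 824 and 3457 without HT fluoxetine males 1, 3 and 5 and 1274 and 1414 without HT vehicle males 2 and 3. For lithium limma called 89 in females (46 higher, 43 lower, edgeR 81, DESeq2 169) and 8 in males (3 higher, 5 lower, edgeR 0, DESeq2 19). A fit to the compared groups alone gave 7 and 0, and surrogate variables 764 and 15. The female lithium count was 44 without HT lithium female 1, 47 without HT vehicle female 1 and 24 without HT vehicle female 3. The male count was 0 without any single one of HT lithium males 2, 4 and 5 or HT vehicle males 3, 4 and 5, 4 without HT lithium male 1 or 3, and 1 without HT vehicle male 1. For genotype in vehicle pups limma called 0 in females (939 at an unadjusted p under 0.05, edgeR 0, DESeq2 0) and 0 in males (525, edgeR 0, DESeq2 1), and surrogate variables gave 1 and 2.

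No interaction of sex with genotype in vehicle pups or with either drug in HT pups passed by limma. The genes closest were the integrin Itgax of dendritic cells at -1.64 for genotype (adjusted p 0.9999), Frk, a Src-family kinase, at 1.34 for fluoxetine (adjusted p 0.985) and the lymphocyte attenuator Btla at 1.37 for lithium (adjusted p 0.9998). Limma called 0 genes for each of these 3 interactions with sex, with 227, 578 and 414 at an unadjusted p under 0.05, edgeR 0, 0 and 0 and DESeq2 0, 2 and 0. Among the added comparisons, which lie across the division of 14 against 45, sex by fluoxetine in WT called 14 genes (4 higher, 10 lower) and sex by genotype under fluoxetine 86 (40 higher, 46 lower, edgeR 62, DESeq2 478). Recovery was not simulated for an interaction, whose median SE was 0.159 against 0.112 for a drug difference within 1 sex. For such a difference at 5 libraries against 5, simulated changes of 1.5 and 2-fold were recovered in 71.6% and 92.4% of genes. The smallest simulated change was recovered in 29.9%. At 10 against 10 the shares were 89.6%, 98.5% and 64.2%.

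Lists without a camera call in any of the 5 comparisons covered glutamatergic synapse, excitatory neuron layer, thalamic neuron, choroid plexus and thyroid hormone response genes besides the serotonin system and the lithium targets. Glutamatergic synapse genes had medians of -0.07 and -0.08 for fluoxetine in HT and WT (20 and 5 of 42 called, 20 and 5 adjusted over the list alone). Excitatory layer genes had -0.05 and -0.10 (9 and 5 of 25 called, 12 and 5 adjusted over the list alone), with means of opposite sign. Thalamic genes had 0.22 and 0.20 (7 and 5 of 12 called, 7 and 5 adjusted over the list alone). Choroid plexus genes had 0.21 and 0.17 (1 and 1 of 6 called, 1 and 3 adjusted over the list alone), and thyroid hormone response genes -0.18 and -0.06 (4 and 1 of 10 called, 5 and 1 adjusted over the list alone). For lithium in HT and WT the medians were 0.03 and 0.0051 for glutamatergic synapse and -0.01 and -0.0046 for excitatory layer genes. They were -0.06 and -0.03 for thalamic, -0.12 and -0.03 for choroid plexus and -0.04 and 0.03 for thyroid hormone response genes.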

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

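In this part, the counts over other divisions of the libraries and the test of the paralogs were set before their results were seen, and the other tests of explanations were chosen after. Dixon's test was applied to 66 groups for 6 measures and picked out 12 values in 10 libraries, where chance alone picks about 1 in 20 groups.

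Fluoxetine in libraries labelled HT came with lower mt-Atp6 and 10 higher bulb markers among 4833 calls, and in WT with 2464. Library batches as the whole cause were argued against in HT, since the WT males outside the 14 libraries moved with a slope of 0.356 on the HT differences where 2 of 100 simulations reached as high. In HT 1038 of the 4833 genes were called with the bulb markers as a covariate (1096 calls). Such a linear term need not take out all of a tissue difference, and the HT comparison also lies across the division. Calls left in HT thus cannot decide whether bulb tissue was the whole cause. In WT 23 calls were left, all among the 2464, as such tissue would give for most of them (median size 0.270 before and 0.0885 after, SE 0.0775 and 0.0804). A batch together with bulb tissue stays open, since all 10 bulb markers were positive in WT males (median 2.19). The r between HT and WT males was 0.462 (simulations -0.44 to 0.45) and fell to 0.106 with the bulb level as a covariate, for which no simulations were run. With the division as a term the slope was 0.158 (jackknife SE 0.247) in HT and 0.584 (jackknife SE 0.170) in WT. The median SE in HT went from 0.0689 to 0.130. The drug itself stays open as well, since the WT males alone gave 0 calls by limma (800 at an unadjusted p under 0.05, edgeR 0, DESeq2 0), so the drug and the division cannot be told apart in HT.

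Under lithium Fkbp5 and Zbtb16 were higher and Rpl17 and Depp1 lower in the libraries labelled HT, among 470 calls. With both the olfactory bulb and striatal marker levels as covariates 363 of the same genes were called. That argues against such tissue as the whole cause only so far as these linear terms take out its share. Lithium is a candidate explanation with a check in separate libraries, since 93.8% of the 470 genes had the same sign in WT (441 genes), where simulations reached 84.9% at most. The HT vehicle controls stay a second open source of part of the count, since it was 102 without HT vehicle female 3 and HT vehicle male 3, the lowest of the 25 pairs of 1 female and 1 male control left out (122 to 677 for the others). Litter and milk dose were not tested.

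Myt1l was higher in the libraries labelled HT by 0.17, 0.21 and 0.28 under vehicle, fluoxetine and lithium, opposite to a loss of the message. A larger share of neurons was argued against by the excitatory layer genes, whose median differences in that order were 0.0330, 0.0299 and 0.0650 (SD of the genes 0.127, 0.107 and 0.106). A change of the chromosome 12 region was argued against by 53 neighbours within 5 Mb, with medians of -0.0133, -0.0242 and 0.00372 (SD 0.146, 0.167 and 0.161). Under vehicle both arguments are weakest, since the Myt1l difference lay little beyond the spread of single genes. Reads taken from the paralogs Myt1 and St18 were argued against by their level. Under lithium they summed to 422.4 normalized counts in WT, less than the gain of 1544 in Myt1l. Their change was -23.33, but at that level the planned test on the change could not have come out otherwise. The genotype, for example by altered transcript structure or feedback on the gene, may raise the count, but the permutation p of 0.0161 under fluoxetine shows a difference and not its origin, and a gene-level count cannot tell exons apart. A label exchanged between whole genotype groups was not tested.

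Other libraries and genes stood out as values only. On the log2 scale Myt1l was 13.27 in HT lithium male 2, 12.60 in HT vehicle female 3, 12.88 in WT lithium female 4 and 12.72 in WT vehicle male 4, each apart from its group. The mitochondrially encoded share was 6.90% in HT fluoxetine male 5 and 11.2% in HT vehicle male 3. The standardized bulb level was 0.282 in WT vehicle female 1. The striatal level was 2.51 in HT fluoxetine female 2, 2.40 in HT vehicle female 3, 1.92 in HT vehicle male 3 and 0.415 in WT vehicle male 3. Xist, the long RNA of the inactive X chromosome, had 1 read in WT fluoxetine female 3, which also lacked the Y-linked Ddx3y, while the other female libraries had at least 15295 reads. The fluoxetine effect differed between genotypes for Gm9794 (-2.88), mt-Atp6 (-0.95), Gm10221 (-3.54), Gm3883 (-5.07) and Gm12671 (-5.89). It differed between WT females and WT males in 14 genes.

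Counts were set against 100 divisions of single libraries, the real one included. As many calls or more came from 1 for fluoxetine in HT (4833 real, 3673 highest other) and 2 for lithium in HT (470, 623). They came from 1 for fluoxetine in WT (2464, 1016) and 1 for lithium in WT (266, 1). Fewer than 5 divisions thus reached each of these 4 counts. Litters are not given in the labels, so a grouping by litter or batch was not excluded as their source. Fewer than 5 divisions also reached the counts for HT fluoxetine against WT vehicle (1 division, 4923 real, 3849 highest other) and HT lithium against WT vehicle (1, 398, 113). So it was for fluoxetine in HT females (2, 1134, 1179) and HT males (3, 2222, 2452) and for lithium in HT females (1, 89, 37) and HT males (1, 8, 2). The fluoxetine by genotype term stood just under that number (4, 5, 219), and edgeR called 1 gene for it. Even among divisions of single libraries chance was not excluded for genotype under fluoxetine (12 divisions, 7 real, 5514 highest other), genotype under lithium (8, 1, 5) or the list calls (5, 61, 70). Counts of 0 were matched by all 100 divisions for genotype in vehicle pups (highest other 3), in vehicle females (1) and males (0), for the lithium by genotype term (1), and for the sex terms of genotype (11), fluoxetine (2248) and lithium (67). Some divisions called as many as 5514, 2248 and 219 genes where the real counts were 7, 0 and 5. Which libraries those divisions put together was not examined.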

How the results depend on the processing

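Chosen after results were seen were the edgeR and DESeq2 tests, the bulb and striatal covariates, the division of 14 against 45 as a term, the sexes taken additively, single sexes for WT fluoxetine and for genotype under fluoxetine, and leaving out 2 libraries. The other alternatives were planned. Where a count moved and no reason is given, the cause was not tested. A pseudocount of 0.5 left all 20 counts within 1.5 times the reported one.

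Of 413 values by gene and comparison, 385 stayed on the same side of the threshold with the same sign under quantile normalization, 403 without a filter, 406 without a trend, 409 with a pseudocount of 5, 351 in a fit to the compared groups alone and 273 with surrogate variables. Of 8097 values with 1 library left out, 7498 stayed, 541 lost the call, 51 gained it and 7 changed sign.

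Surrogate variables turned the sign of 17 values. For fluoxetine in HT these were Ms4a15 -0.62, Eomes -0.31, Tbx21 -0.017, Cdhr1 -0.11, Chrna10 -0.13, Tubb2b -0.00017 and Slc18a2 -0.24, and in WT Frmd7 -0.39, Hcrtr1 0.022, Islr -0.060, Dcx -0.23, Notch2 -0.10, Lgr5 -0.053, Nkd2 -0.025 and Sp8 -0.51. Myt1l turned to -0.0063 in the lithium by genotype term and 0.0065 in the lithium by sex term, and neither had passed before. Among lists the direction turned for cytosolic ribosomal proteins under genotype (adjusted p 0.898) and lithium in WT (0.934), immature neuron under fluoxetine in HT (0.891) and WT (0.0683), oxidative phosphorylation under fluoxetine in HT (0.586) and WT (0.656), cell cycle under lithium in HT (0.934), and Notch pathway (0.457) and Wnt targets (0.629) under fluoxetine in WT. Leaving out 1 library turned Myt1l in terms that had not passed. The fluoxetine by sex term ran from -0.049 without HT vehicle female 3 to 0.11, with -0.017 without HT fluoxetine female 2 and -0.042 without HT fluoxetine male 1. The lithium by sex term ran from -0.13 to 0.028 without HT vehicle male 3, with 0.00022 without HT lithium female 3. The fluoxetine by genotype term ran from -0.0065 without HT vehicle female 3 to 0.082, and the genotype by sex term from -0.11 to 0.047 without HT vehicle female 3.

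Counts of called genes under quantile normalization were 2 for genotype in vehicle pups, 2 for genotype under lithium and 0 for lithium in HT males. The last was also 0 without a filter, without a trend and with a pseudocount of 5. The fit to the compared groups alone gave 2244 and 3677 for fluoxetine in HT and WT, and 188 and 617 for lithium in HT and WT. It gave 3 for the fluoxetine by genotype term, 2 for genotype under lithium, 3147 for HT fluoxetine and 695 for HT lithium against WT vehicle. By sex it gave 19 and 7 for fluoxetine and 7 and 0 for lithium in HT females and males. Fewer libraries to estimate the spread do not account for the whole change. The pooled HT counts fell (4833 to 2244 and 470 to 188), while the WT counts rose (2464 to 3677 and 266 to 617). The adjusted p-values printed for HT by limma rest on the spread shared by all 12 groups.

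Surrogate variables gave 27 for genotype in vehicle pups (1 in females, 2 in males), 1819 and 251 for fluoxetine in HT and WT, 1001 and 844 for lithium in HT and WT, 103 and 94 for genotype under fluoxetine and lithium, 1813 and 1329 for HT fluoxetine and HT lithium against WT vehicle, 238 for fluoxetine in HT males, and 764 and 15 for lithium in HT females and males. The bulb level as a covariate gave 1096 and 23 for fluoxetine in HT and WT, 453 for lithium in WT, 12 for genotype under fluoxetine, 901 for HT fluoxetine against WT vehicle and 439 and 46 for fluoxetine in HT females and males, and with the striatal level added 1360, 20, 506, 15, 790, 550 and 129. Without HT vehicle female 3 and HT vehicle male 3 lithium gave 102 in HT, 44 in HT females and 0 in HT males.

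With the division as a term the count was 1 for genotype in vehicle pups and 0 for fluoxetine in HT, fluoxetine in WT, genotype under either drug, HT fluoxetine against WT vehicle and the fluoxetine by genotype term. With sex additive and no such term it was 1 for genotype in vehicle pups and 0 for genotype under lithium and the fluoxetine by genotype term. By limma WT males alone gave 0 for fluoxetine. Genotype under fluoxetine gave 0 in females (edgeR 0, DESeq2 3) and 302 in males (edgeR 220, DESeq2 493), whose comparison lies across the division. The edgeR test gave 1 for the fluoxetine by genotype term, 4 for genotype under fluoxetine and 0 for lithium in HT males. DESeq2 gave 5 for genotype in vehicle pups (1 in males), 3 for the fluoxetine by genotype term, 2 for genotype under lithium, 169 and 19 for lithium in HT females and males and 2 for the fluoxetine by sex term.

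List calls went from 61 to 0 with an estimated correlation and 19 with fry. The r between genotype and drug differences was -0.0082 for fluoxetine and -0.038 for lithium with the HT vehicle libraries split into separate parts, which takes away the shared controls. The r between HT and WT was 0.568 for fluoxetine with the bulb level as a covariate, 0.462 with WT males alone and 0.106 with both (0.641 for WT females with the bulb level), and 0.442 for lithium at a mean of at least 200.

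The replicate numbers did not pair the libraries. Residuals of libraries with the same number in different groups correlated with a mean r of 0.0085 over 319 pairs, against -0.0018 for 1276 pairs with different numbers, and 16 of 59 libraries correlated best with their own number. With the number as a block the count was 3 for genotype in vehicle pups and 4 for lithium in HT males, and the other 18 counts stayed within 1.5 times.

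With 1 library left out, counts ran from 3514 to 5481 for fluoxetine in HT, 1086 to 2843 for fluoxetine in WT, 177 to 721 for lithium in HT, 111 to 315 for lithium in WT, 0 to 3 for genotype in vehicle pups, 5 to 9 for genotype under fluoxetine, 0 to 3 for genotype under lithium and 3 to 6 for the fluoxetine by genotype term. They ran from 3562 to 5682 for HT fluoxetine and 239 to 426 for HT lithium against WT vehicle, 539 to 1336 and 426 to 3457 for fluoxetine in HT females and males, 24 to 118 and 0 to 7 for lithium in HT females and males, and 45 to 66 for list calls. They stayed at 0 for genotype in vehicle females and males, the lithium by genotype term and the 3 sex terms. The Myt1l difference ran from 0.16 to 0.22 under vehicle, 0.18 to 0.25 under fluoxetine and 0.26 to 0.30 under lithium. The r ran from -0.30 to -0.16 and -0.52 to -0.37 between genotype and fluoxetine or lithium differences, and from 0.739 to 0.806 and 0.243 to 0.354 between HT and WT for fluoxetine and lithium. At 25088446 to 35858365 reads per library the counting error is largest for the genes nearest the minimum mean of 10.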

Other observations

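The tests in this part were chosen after the results were seen. Genes that differed under lithium in both genotypes were followed first. Of the 19 genes plotted for lithium, the co-chaperone Fkbp5 stood at 0.81 (SE 0.111) in HT and 0.52 (SE 0.111) in WT. In the same order the FOXO-induced gene Depp1 stood at -1.06 and -0.997 (SE 0.206 each) and the synaptic pentraxin Nptx2 at 0.33 and 0.53 (SE 0.0701 each). Among the 210 genes called higher in HT, 202 (96.2%) had the same sign in WT, and among the 260 called lower, 239 (91.9%) did.

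The WT males given fluoxetine are the only fluoxetine libraries outside the division of 14 against 45, and single genes gave 0 calls there by limma. At unadjusted p, the clock repressor Nr1d1 stood at -0.49 (p 7.02e-05), the ATP synthase subunit Atp5e at -0.25 (p 0.000691) and the monoamine transporter Slc18a2 at 1.84 (p 0.00331). By camera with the preset correlation, adjusted over the 31 lists of this fit, cholesterol synthesis (adjusted p 1.05e-07), circadian clock (3.20e-06) and microglia genes (7.81e-05) were lower as sets. None passed with an estimated correlation. Myelin (0.641), astrocyte (0.958) and endothelial and mural genes (0.796) did not pass with the preset one. Of the 12 named genes with the highest fluoxetine differences in HT, 12 had the same sign in WT males, and of the 12 with the lowest, 6.

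Gene composition was set against the differences, and what its rho would be without any change was not tested. The Spearman rho across 16535 genes between the log2 difference and the share of G and C was 0.299 for genotype under vehicle, 0.338 for lithium in WT, 0.0308 for lithium in HT, -0.0570 for fluoxetine in HT and 0.0348 for fluoxetine in WT. With exon length the rho was -0.154, -0.146, 0.0535, 0.114 and 0.0744 in the same order.

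No library repeated another, over 116 pairs within groups.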
